A study of Arabidopsis thaliana with 6 samples.

How the data were processed

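Total RNA from whole Arabidopsis thaliana plants was amplified, labelled with biotin and hybridised to Affymetrix ATH1 arrays, which read each transcript with a set of short oligonucleotide probes. The 6 arrays fell into 3 groups of 2 by their labels: wild type of the Wassilewskija accession, the octopus mutant, and a line overexpressing OCTOPUS. Per the labels' protocols, plants grew on a medium named MS/2 at 20 °C and 70% hygrometry without treatment. The labels give neither the age of the plants, nor the accession of the overexpressor, nor whether the replicates of a group were separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

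The deposited values are log2 GCRMA expression values, 1 per probe set and array, made by the authors with GCRMA per the submitters' processing notes, which name no version. GCRMA subtracts a background modelled from probe sequence, normalises the arrays and summarises the probes of each set. The log2 scale was inferred from the values, which lay between 1.82 and 14.3 on the 6 arrays. Which arrays were normalised together is not given in the sources used here. The highest value was 14.2679 on each wild-type and mutant array, and 14.2937 and 14.2061 on the overexpressor arrays. The table prints most values to 2 decimals and some probe sets to more, 2096 of them in the wild-type and mutant arrays and 551 in the overexpressor arrays. No detection calls were used here. The 25th percentile of an array lay between 2.54 and 2.70, and values near it are treated as close to the floor, where a fold is limited by background. The number of arrays limits the precision.

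Probe sets were named through the platform annotation table, in which 13513 probe sets name 1 gene, 503 name several and 8794 of the 22810 on the array are not listed. Of the probe sets naming 1 gene, 13436 were matched by gene number to the TAIR10.1 annotation, which gave current symbols, locus names and the order of genes, and 77 kept the name of the table. Probe sets with several names or none were tested but are not named. No coordinates are printed because the build behind the array is not given.

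Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided) on the log2 values as deposited. All 6 arrays entered one fit without covariates, so that the 3 groups shared one estimate of the spread per probe set with 3 residual degrees of freedom, to which the prior added 3.98. The 64 control probe sets were left out and the 12363 probe sets with a mean of at least 4 over the 6 arrays were tested. A probe set passed at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Errors of changes are standard errors of that fit, and errors of group levels are SDs over 2 arrays.

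The comparisons, the tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined, apart from those said to be added. Named genes are OCTOPUS in every comparison and, against wild type, the 10 largest rises and 10 largest falls in log2 change among probe sets that passed, name 1 gene and whose arrays do not overlap between the groups. For overexpressor against mutant the rule takes 5 and 5. Up to 4 members of each described list with the smallest p were added. Of 26 gene lists with 412 entries, few could be measured by name: 55 of 408 genes had a named probe set and 33 were tested. The 5 lists with at least 3 tested members, on procambium and vascular patterning, brassinosteroid-induced growth genes, auxin response, photosynthesis, and cold and abscisic acid, were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether the members of a list move on balance one way, were run beside it. With an estimated correlation camera p rose even where the estimate was negative. For the brassinosteroid-induced growth genes in the overexpressor against wild type it rose from 0.0396 to 0.128, at an estimate of -0.228. A call lost with an estimated correlation therefore need not come from correlation between members. Of the other lists only values of single members are given, apart from the anthocyanin and flavonoid list, which had enough members only without a filter. Plastid-encoded transcripts and gene families formed from the letters of the symbols, with at least 6 tested members, were added after the data were examined.

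Changes of the mutant and of the overexpressor against the shared wild-type arrays were correlated across probe sets and set against 100 simulations of unchanged groups. In 100 further simulations, added after the data were examined, unchanged groups were fitted in the same way, and as many probe sets of smallest p as had passed were taken per comparison, to count shared probe sets and those with wild type between the lines. Changed genes were counted in windows of 50 neighbouring measured genes and set against 1000 random relabellings. The alternatives were no filter, a mean of at least 6, no trend, a robust prior, the replicate number as a block, only the 2 groups compared, quantile normalization or median centring on top, each array left out in turn, and an added fold threshold. A block with exchanged mutant numbers and a fit without the probe sets printed to more decimals were added later.

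The tests were tried on simulated data built from the real means and spreads, with 200 changed probe sets among 12363. In the simulated mutant comparison 17.9% of changes of 0.5 log2 units, 86.6% of changes of 1 and 97.0% of changes of 2 were recovered, and 5.63% of the calls were false. In the simulated comparison of overexpressor and wild type the shares were 16.4%, 65.7% and 100%, with 9.02% false calls. In that of overexpressor and mutant they were 19.4%, 88.1% and 100%, with 7.38% false calls. Of 100 simulated lists of 4 members shifted by 1 log2 unit in the mutant, all 100 passed an unadjusted 0.05 with camera. Of 100 unshifted lists 3 passed. Means and spreads carry no correlation between probe sets, so this does not give camera's false rate for lists whose members move together. The estimated correlation was 0.248 in the cold and abscisic acid list, 0.343 in the photosynthesis list and 0.835 in the auxin response list. It was 0.853 in the procambium and vascular patterning list and -0.228 in the brassinosteroid-induced growth genes.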

Results

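Transcript levels were measured in 6 samples of whole plants: 2 of wild type, 2 of the octopus mutant and 2 of a line overexpressing OCTOPUS. OCTOPUS (OPS, AT3G09070) encodes a plasma membrane protein needed for phloem formation, and the labels describe the mutant as impaired in phloem differentiation and in the patterning of the vasculature. The comparisons ask which transcripts differ in the mutant, in the overexpressor, and between these 2 lines. Array medians lay between 4.40 and 4.49 on the log2 scale. Across the tested probe sets the arrays of a group correlated at 0.987 in wild type, 0.989 in the mutant and 0.984 in the overexpressor, and arrays of different groups at 0.939 to 0.975.

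The OPS transcript was high in the overexpressor and near the floor elsewhere. Its level was 9.68 ± 0.22 (SD, n = 2) in the overexpressor, 2.56 ± 0.13 (SD, n = 2) in wild type and 2.50 ± 0.04 (SD, n = 2) in the mutant. The overexpressor exceeded wild type by 7.11 log2 units (SE 0.171, limma adjusted p = 7.78e-06), a 138-fold difference whose size is limited by the floor, and the mutant by 7.17 (SE 0.171). The mutant differed from wild type by -0.065 (SE 0.171, adjusted p = 0.838). Since wild type already stood near the floor, and where the probes lie against the mutation is not in the labels, OPS checks the label of the overexpressor and does not check that of the mutant.

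**Figure D1:**
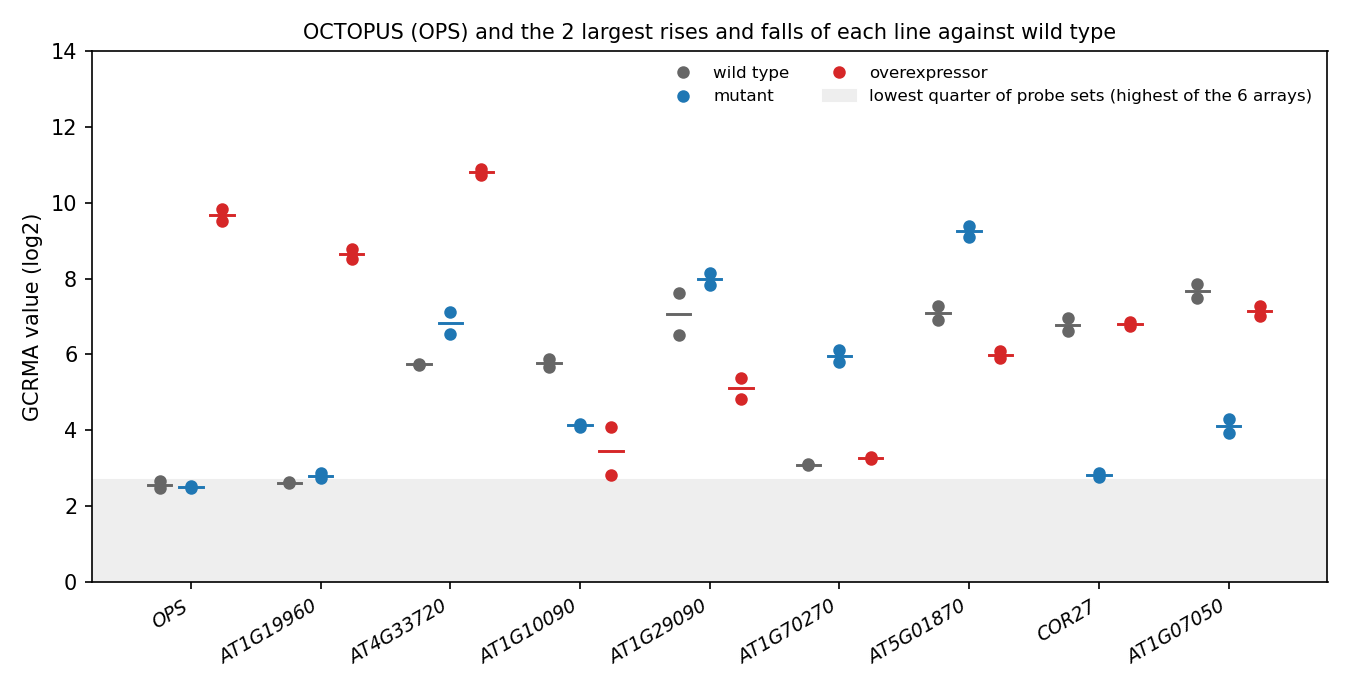
GCRMA level (log2, vertical axis) of OPS and of the 2 largest named rises and falls of each line against wild type; each point is 1 array, each short line the mean of 2 arrays, and the grey band reaches up to the highest of the 25th percentiles of the 6 arrays (2.70). OPS and AT1G19960 lie near the floor in wild type and mutant and at 9.68 and 8.66 in the overexpressor, and COR27 lies at 2.83 in the mutant against 6.79 in wild type.

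In the mutant, transcripts of COR27, a cold-induced gene that also acts in the circadian clock, fell by 3.96 log2 units against wild type (SE 0.165, adjusted p = 0.000357, n = 2 per group), which is 15.6-fold with the mutant close to the floor. Its homologue AT4G33980, known as COR28, fell by 2.94 (SE 0.271, adjusted p = 0.00239), or 7.65-fold. AT1G07050, which encodes a protein with a CCT motif, fell by 3.57 (SE 0.196), or 11.8-fold, and AT1G19530 fell by 3.42 (SE 0.319). THIC, an enzyme of thiamine synthesis, fell by 2.50 (SE 0.201, adjusted p = 0.00149), from 11.2 ± 0.48 to 8.69 ± 0.05 (SD, n = 2 each).

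AT1G64590 fell 6.00-fold, AT4G32340 fell 5.19-fold, the peroxidase AT2G39040 fell 4.81-fold, AT4G16146 fell 4.76-fold and AT4G36610 fell 4.23-fold. The largest named rises were smaller. AT1G70270 rose by 2.86 log2 units (SE 0.171, adjusted p = 0.00108), or 7.26-fold. The lipid transfer protein gene AT5G01870 rose 4.44-fold (SE 0.175 log2 units) and AT1G73600, of the phosphoethanolamine N-methyltransferase family, rose 4.21-fold (SE 0.146). PPDK, pyruvate orthophosphate dikinase, rose 4.12-fold (SE 0.186), AT3G15650 rose 3.97-fold and ASPGB1, an asparaginase, rose 3.73-fold. PPDK is among the probe sets printed to more decimals, whose replicate spread is taken up at the end. AT5G48490, of the lipid transfer family, rose 3.97-fold with a larger error (SE 0.508, adjusted p = 0.0456), the cysteine protease AT2G27420 rose 3.88-fold, AT1G13650 rose 3.68-fold and AT4G32950, a protein phosphatase gene, rose 3.52-fold. Among probe sets without a gene name, the largest fall was -6.35 (SE 0.605; -7.33 without mutant array 1 and -5.37 without mutant array 2) and the largest rise 3.99 (SE 0.326). Of these 20 named changes 5 lost their call with single arrays left out. AT5G48490 and AT1G13650 did so without either mutant or either overexpressor array (highest adjusted p = 0.226 and 0.18), AT2G27420 and AT2G39040 without any of the wild-type or mutant arrays (0.133 and 0.153) and AT4G36610 without mutant array 1 (0.073). The rise of AT5G48490 was 2.13-fold without wild-type array 1 and 7.41-fold without wild-type array 2, and that of AT1G13650 was 2.17-fold and 6.23-fold.

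Of the cold and abscisic acid list, 2 of 3 tested members fell in the mutant, and 3 when adjusted over the list alone. The dehydrin genes COR47 and LTI30 fell in the mutant: COR47 fell by 1.25 log2 units (SE 0.147, adjusted p = 0.00441) and LTI30 fell by 1.13 (SE 0.165, adjusted p = 0.00805). COR15B differed by -1.26 (SE 0.355, adjusted p = 0.0595). The list had a median change of -1.25 (camera adjusted p = 0.00914; fry adjusted p = 0.0297). Its call was lost with an estimated correlation (adjusted p = 0.411 with an estimated correlation). The call of LTI30 was lost without mutant array 1 (adjusted p = 0.082) and without mutant array 2 (0.0626), and COR47 kept its call without each of the 6 arrays.

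No other list passed camera in the mutant, though the auxin response list did without wild-type array 2 (adjusted p = 0.0362; adjusted p = 0.657 with an estimated correlation). In the auxin response list 1 of 3 members rose, also over the list alone: GH3.3, which conjugates auxin to amino acids, rose 2.39-fold (SE 0.158, adjusted p = 0.00515), while WES1 differed by 0.36 and HAT2 by 0.23 (camera adjusted p = 0.11). Of the 4 brassinosteroid-induced growth genes 1 rose, and 1 rose and 1 fell over the list alone. The expansin gene EXPA8 rose 2.59-fold (SE 0.254, adjusted p = 0.0165), EXPA4 differed by 0.21, and XTH18 by -0.55 (adjusted p = 0.0683; camera adjusted p of the list 0.498). In the photosynthesis list 2 of 8 rose, and 2 rose and 1 fell over the list alone: the antenna gene LHCB4.2 rose 2.48-fold (SE 0.277) and PSBY rose 1.29-fold (SE 0.0876), with RCA at 0.18 and ATPC1 at -0.23 (camera adjusted p = 0.498). In the procambium and vascular patterning list none of 3 passed, with CLE41 at 0.24, PHV at 0.21 and LHW at 0.06 (camera adjusted p = 0.498).

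Of the 16 genes of the anthocyanin and flavonoid list 4 had a named probe set, and all 4 lay under the filter. Without a filter these 4 passed in the mutant, with a median of 0.61 (camera adjusted p = 0.0317; adjusted p = 0.296 with an estimated correlation), and 2 of 4 members rose. DFR, dihydroflavonol reductase, rose by 1.75 log2 units (SE 0.21, adjusted p = 0.016), from 2.29 to 4.04, and UF3GT rose by 0.65 (SE 0.0813, adjusted p = 0.0183), close to the floor. AT4G14090 differed by 0.57 (adjusted p = 0.435) and AT5MAT by 0.01. In the overexpressor none of the 4 passed against wild type, with DFR at -0.075.

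Among lists with fewer tested members, SWEET11, a sucrose exporter of phloem loading and the 1 tested gene of the phloem list, fell 1.72-fold in the mutant (SE 0.123, adjusted p = 0.0102). BCAT4, of methionine chain elongation in glucosinolate synthesis, rose 1.87-fold (SE 0.191, adjusted p = 0.0258), and AT2G31790, of the same pathway, differed by 0.45 (adjusted p = 0.0889). The xylan synthesis gene GUT2 differed by -0.62 (adjusted p = 0.29), WRKY53 by -0.34, SAG101 by 0.06, AT5G48570 of the heat shock list by -0.38, STZ of the touch and early stress list by -0.54 and the clock gene GI by -0.29 (adjusted p = 0.286). Of the markers of particular cell types none passed: the root marker PYK10 differed by -0.045 (SE 0.0973), the root hair expansins EXPA7 and EXPA18 by -0.42 and -0.19, and FMA of the stomatal lineage by -0.48 (adjusted p = 0.155).

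COR47 was the 1 of 8 list members changed in the mutant whose call held without each array in turn. Without mutant array 1 the adjusted p was 0.0593 for GH3.3, 0.0851 for SWEET11, 0.105 for EXPA8, 0.119 for PSBY, 0.145 for BCAT4 and 0.151 for LHCB4.2. Without mutant array 2 it was 0.0564 for GH3.3, 0.114 for EXPA8, 0.202 for PSBY, 0.138 for BCAT4 and 0.133 for LHCB4.2. PSBY and BCAT4 also lost their calls without wild-type array 1 (0.143 and 0.0627) and without wild-type array 2 (0.0714 and 0.124), as SWEET11 did without wild-type array 2 (0.0534).

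In all, 1736 of 12363 probe sets changed in the mutant against wild type, 846 higher and 890 lower, of which 493 changed at least 2-fold (183 higher and 310 lower). The control probe set of the 25S ribosomal RNA stood at 8.03 and 11.2 in the mutant arrays against 6.42 and 5.86 in wild type. The count was lower without any 1 of the wild-type or mutant arrays, and falls prevailed more without either mutant array. Each such fit leaves 1 array in a group, so the lower count need not rest on a particular array. Without a filter on low values the count was 1009, and with added quantile normalization more probe sets were higher than lower, 923 against 884.

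In the overexpressor, apart from OPS, the named transcript with the largest rise against wild type was AT1G19960, by 6.04 log2 units (SE 0.162, adjusted p = 1.12e-05, n = 2 per group), a 65.8-fold rise from near the floor. AT4G33720, which encodes a protein related to the pathogenesis-related PR-1 family, rose by 5.08 (SE 0.196, adjusted p = 5.19e-05), from 5.74 ± 0.01 to 10.8 ± 0.11 (SD, n = 2 each). AT2G41090, a calmodulin-like gene, rose by 4.15 (SE 0.160), or 17.7-fold, and AT1G26250, an extensin-like gene, rose 12.8-fold (SE 0.193). AT3G28510, which encodes an AAA-type ATPase, rose by 3.79 (SE 0.259), AT5G41280, of a family of cysteine-rich secreted proteins, by 3.37 (SE 0.148), cwINV6, of the cell wall invertase family, by 3.31 (SE 0.206) and AT1G13470 by 3.04 (SE 0.154). AT3G60420 rose by 3.81 (SE 0.165) on one probe set, while its second probe set stayed near the floor at 2.50 ± 0.05 against 2.44 ± 0.02 (SD, n = 2 each).

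Falls in the overexpressor were smaller. AT1G10090 fell by 2.31 log2 units (SE 0.380, adjusted p = 0.0321), with a difference of -0.39 on its second probe set. Its change was -2.96 without overexpressor array 1 and -1.67 without overexpressor array 2. The cysteine protease genes AT1G29090 and CP1 fell 3.89-fold (SE 0.361, adjusted p = 0.0446) and 2.63-fold (SE 0.192). The fatty acid desaturase family gene AT1G06100 fell 3.04-fold, AT4G01390 fell 3.02-fold, and AT5G54130 fell 2.96-fold with -0.47 on its second probe set. The plastid genes atpF and atpH, for subunits of the ATP synthase, fell 3.34-fold (SE 0.190) and 3.23-fold (SE 0.24), petG of the cytochrome bf complex fell 3.26-fold (SE 0.198) and psaA of photosystem I fell 2.89-fold (SE 0.276). The 3' signal of the GAPDH control exceeded its 5' signal by 1.92 and 1.72 log2 units in the overexpressor arrays, 1.42 and 1.12 in wild type and 1.80 and 1.39 in the mutant. Among probe sets without a gene name, the largest rise was 6.82 (SE 0.141) and the largest fall -2.79 (SE 0.305).

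Each of the 10 named falls in the overexpressor lost its call with at least 1 array left out, while the 9 named rises other than OPS passed under each of the 13 or 14 alternatives in which they were tested. The call of atpF was lost without overexpressor array 2 (adjusted p = 0.056), that of petG without either wild-type array (highest adjusted p = 0.0945) and that of AT4G01390 without either wild-type array or overexpressor array 2 (0.0754). CP1 lost its call without wild-type array 2, either mutant array or overexpressor array 2 (0.112), and atpH without wild-type array 1, either mutant array or overexpressor array 2 (0.123). AT1G10090 lost it without any of the wild-type or mutant arrays (0.178), and AT1G06100 and AT5G54130 without these or overexpressor array 2 (0.188 and 0.174). Among these fits AT1G29090 passed only without wild-type array 1 (0.206 at its highest), and psaA only without wild-type array 2 (0.2).

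No list fixed beforehand passed camera in the overexpressor against wild type with all arrays and the filter. The cold and abscisic acid list passed without a filter (adjusted p = 0.0262) and without either mutant array (0.0427 each), and the brassinosteroid-induced growth genes passed without wild-type array 1 (0.014). With an estimated correlation these adjusted p were 0.398, 0.432, 0.432 and 0.468. In the cold and abscisic acid list none of 3 members passed and 3 were lower when adjusted over the list alone, with COR47 at -0.48, LTI30 at -0.48 and COR15B at -1.31 (camera adjusted p = 0.0684). Of the brassinosteroid-induced growth genes none of 4 passed and 2 were lower over the list alone, with EXPA4 at -1.01 (adjusted p = 0.0744), XTH18 at -0.52, HAT2 at -0.32 and EXPA8 at -0.24 (camera adjusted p = 0.099). None of the 8 photosynthesis genes passed, with PSAN at -0.29, PSAE-1 at -0.18, ATPC1 at -0.12 and PSBW at -0.11 (camera adjusted p = 0.862). None of the 3 genes of the procambium and vascular patterning list passed, with PHV at -0.29, CLE41 at 0.12 and LHW at -0.10 (camera adjusted p = 0.862). The auxin response list had GH3.3 at 0.18, its median and mean were both -0.07, and camera placed it up (adjusted p = 0.869).

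WRKY53, a transcription factor gene of senescence and defence, rose 3.13-fold in the overexpressor (SE 0.195, adjusted p = 0.0108), a call lost without wild-type array 1 (adjusted p = 0.0763), wild-type array 2 (0.0731) or overexpressor array 2 (0.073). SAG101, also of the salicylic acid defence list, differed by 0.46 (adjusted p = 0.212). SWEET11 differed by -0.29 (adjusted p = 0.243), GUT2 by -0.02, BCAT4 by -0.50, AT2G31790 by -0.12, GI by 0.14, STZ by 0.33 and AT5G48570 by -0.12, none of which passed. The cell type markers did not pass either, with PYK10 at -0.42 (adjusted p = 0.0805), EXPA7 at -0.55, EXPA18 at -0.04 and FMA at -0.48.

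In all, 313 of 12363 probe sets changed in the overexpressor against wild type, 184 higher and 129 lower, of which 185 changed at least 2-fold (133 higher and 52 lower). Whether the overexpressor arrays were processed apart from the others is not known. This count, and that against the mutant below, may therefore hold differences of processing. The count was 57 without wild-type array 1 (53 higher and 4 lower), 109 without wild-type array 2 (86 and 23), 80 without mutant array 1 (70 and 10), 75 without mutant array 2 (67 and 8) and 83 without overexpressor array 2 (76 and 7). Without overexpressor array 1 it was 373 and the balance turned, to 142 higher and 231 lower. The count was 226 without a filter (170 higher and 56 lower), 191 with a mean of at least 6 (90 of them lower) and 75 in a fit of the 4 arrays compared, 67 higher and 8 lower. With the replicate number as a block it was 118 (91 higher and 27 lower), and with the mutant numbers exchanged 771 (382 and 389).

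Between the overexpressor and the mutant, whose loss of OPS rests on its label, OPS was followed among named rises by AT1G19960, higher by 5.85 log2 units (SE 0.162, adjusted p = 1.39e-05, n = 2 per group). After it came AT3G60420 by 4.58 (SE 0.165), AT4G33720 by 3.99 (SE 0.196) and the lipid transfer family gene AT5G55450 by 3.98 (SE 0.300). Lower in the overexpressor than in the mutant were AT5G01870, which fell by 3.26 (SE 0.175, adjusted p = 0.000193), AT1G29090, which fell by 2.89 (SE 0.361), AT1G70270, which fell by 2.67 (SE 0.171), AT2G27420, which fell by 2.60 (SE 0.423), and AT1G73600, which fell by 2.59 (SE 0.146). The call of AT2G27420 was lost without mutant array 2 (highest adjusted p = 0.067) and without overexpressor array 2. COR27 was higher by 3.97 (SE 0.165) and THIC by 2.50 (SE 0.201).

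Of the cold and abscisic acid list 2 of 3 members were higher in the overexpressor than in the mutant, also over the list alone, COR47 1.71-fold (SE 0.147, adjusted p = 0.0152) and LTI30 1.58-fold (SE 0.165), with COR15B at -0.055 (camera adjusted p = 0.124). Of the brassinosteroid-induced growth genes 2 of 4 fell, also over the list alone, EXPA8 3.06-fold (SE 0.254) and EXPA4 2.34-fold (SE 0.226), with HAT2 at -0.55 and XTH18 at 0.025 (camera adjusted p = 0.12; fry adjusted p = 0.0251). In the auxin response list 1 of 3 fell, also over the list alone, GH3.3 2.11-fold (SE 0.158; camera adjusted p = 0.12), and in the photosynthesis list 1 of 8 fell, also over the list alone, LHCB4.2 2.31-fold (SE 0.277; camera adjusted p = 0.215). None of 3 procambium and vascular patterning genes passed, with PHV at -0.49 (camera adjusted p = 0.257). Without mutant array 2 the cold, brassinosteroid and auxin lists each passed camera (adjusted p = 0.0487; adjusted p = 0.393, 0.393 and 0.51 with an estimated correlation), and without overexpressor array 2 the auxin list did (0.0458; adjusted p = 0.459 with an estimated correlation). Outside these lists WRKY53 rose 3.97-fold (SE 0.195), SWEET11 rose by 0.49 log2 units (SE 0.123), BCAT4 fell 2.64-fold (SE 0.191), AT2G31790 fell 1.49-fold (SE 0.147) and the root marker PYK10 fell 1.30-fold (SE 0.0973, adjusted p = 0.0395). GUT2 at 0.59, GI at 0.43 and FMA at 0.00 did not pass.

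WRKY53 was the 1 of 11 list members differing between overexpressor and mutant whose call held without each array in turn. The other 10 lost it without mutant array 1, with adjusted p from 0.0519 for BCAT4 and 0.0527 for EXPA4 to 0.175 for LTI30 and 0.186 for SWEET11. Without mutant array 2 it was lost for those but COR47 (0.221 for PYK10 at its highest), and without overexpressor array 2 for SWEET11, EXPA4, LHCB4.2, PYK10 and AT2G31790 (0.144 at its highest). Without overexpressor array 1 it was lost for SWEET11, LHCB4.2, COR47, LTI30 and AT2G31790 (0.106 at its highest), and without either wild-type array for SWEET11, LTI30 and AT2G31790 (0.0578 at its highest).

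The overexpressor and the mutant differed in 2269 probe sets, 1088 higher and 1181 lower in the overexpressor, of which 642 differed at least 2-fold (378 higher and 264 lower). The count was 503 without mutant array 1 (312 higher and 191 lower), 363 without mutant array 2 (256 and 107) and 1095 without overexpressor array 2 (601 and 494), so that the balance turned in each, as it did without a filter (796 and 735). Of these 2269, wild type lay between the other groups in 1521 (67.0%), 676 highest and 845 lowest in the overexpressor, and outside them in 748. Selecting probe sets for a difference between the lines by itself favours this. Among as many probe sets of smallest p in simulated unchanged groups, wild type lay between in 66.4% on average (64.1% to 68.8%). Those groups held noise alone, so they do not give the share expected where 1 line has changes of its own. Whether transcripts were ordered by OPS cannot be told from the share. The number between was 352 without mutant array 1 (200 highest and 152 lowest in the overexpressor) and 211 without mutant array 2 (140 and 71), where the balance turned, 716 without overexpressor array 2 (356 and 360) and 1006 without a filter.

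PPDK, named here like the next genes after the values were seen, rose in both lines against wild type, by 2.04 log2 units in the mutant and 2.13 in the overexpressor, as did AT4G27300, by 1.73 and 1.86, and AT3G22060, by 1.30 and 2.81. The PPDK values are of the kind printed to more decimals, whose replicate spread differed from that of the others. AT1G10090 fell in both, at -1.63 in the mutant and -2.31 in the overexpressor, and so did atpF, at -1.21 and -1.74. AT5G01870 went apart, at 2.15 in the mutant and -1.11 in the overexpressor, and so did AT5G55450, at -1.50 and 2.48. Over all calls 27 probe sets were higher in both lines and 52 lower in both, where independent lists would share 12.6 and 9.29. Another 5 were higher in the mutant and lower in the overexpressor and 10 the opposite, where independent lists would share 8.83 and 13.2. In simulated unchanged groups, which passed the test almost nowhere, lists of the same sizes by smallest p shared 78.3 probe sets higher in both, 75.5 lower in both and 4.06 in opposite directions on average. Part or all of the excess over independent lists may come from the wild-type arrays, which both comparisons share. How much cannot be told, since the simulated lists held noise alone and the 2 wild-type arrays were not split.

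Across probe sets, which are not independent replicates, the 2 sets of changes correlated at r = 0.259. Simulated unchanged groups that shared a simulated wild type gave 0.497 on average. A shared control of equal noise gives such a value by itself, and changes in only 1 line lower it. The lower r is therefore no sign that the lines were less alike than unchanged groups. The covariance of the 2 sets of changes was 0.0532 against 0.0174 in the simulations (at most 0.0186), a difference of 0.0358. The simulated noise was drawn independently for each probe set and array, so a difference common to both wild-type arrays is not in it. The covariance therefore cannot tell changes shared by the lines from such a difference. Without single arrays r lay between 0.177 (without mutant array 1) and 0.376 (without wild-type array 2).

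**Figure D2:**
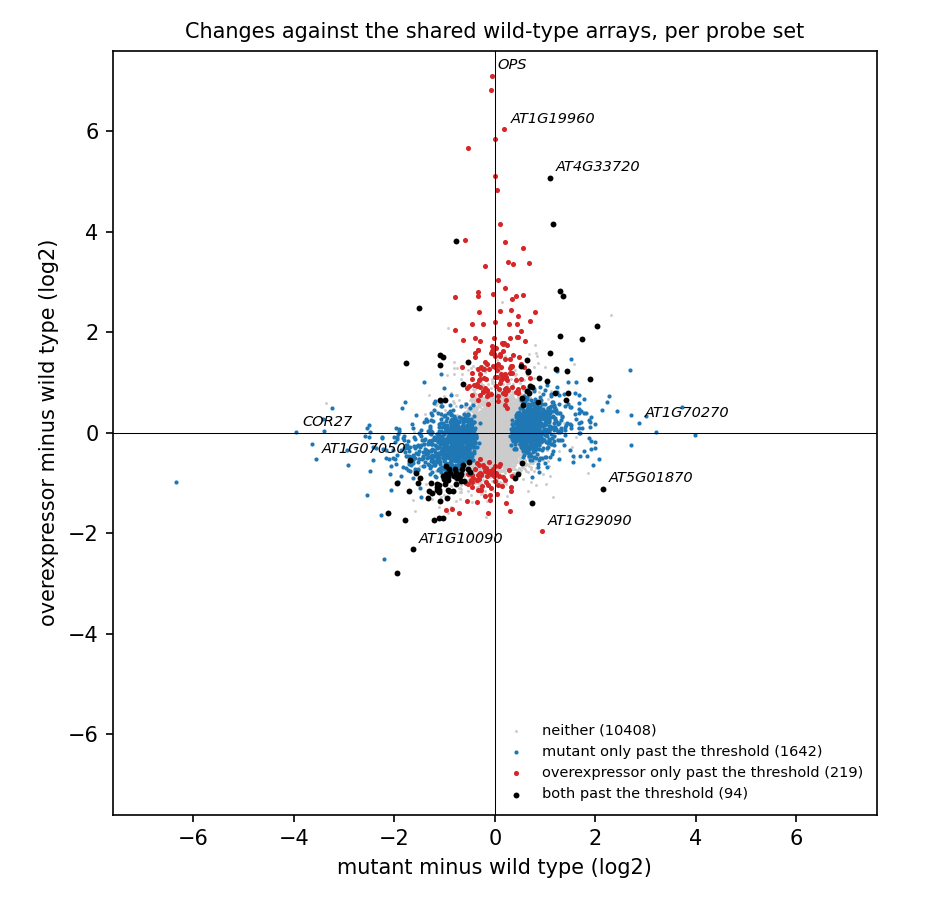
Change of the mutant (horizontal axis) and of the overexpressor (vertical axis) against wild type in log2 units, 1 point per tested probe set, coloured by which comparison passed an adjusted p of 0.05, with the largest named changes labelled. The 1642 probe sets past the threshold in the mutant alone spread along the horizontal axis, the 219 past it in the overexpressor alone along the vertical axis, and 94 passed in both.

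A last comparison asked whether changed genes lie together on the chromosomes, OPS being on chromosome 3. Of the 20 measured genes on either side of OPS, 4 changed in the mutant against 5.62 expected from the share of all tested probe sets, among them LHCB4.2. None of the 40 changed in the overexpressor against wild type, with 1.01 expected, and 6 differed between overexpressor and mutant, with 7.34 expected. The fullest window of 50 neighbouring measured genes held 15 genes changed in the mutant and 5 changed in the overexpressor, and the medians of random relabellings were 15 and 5. The windows covered the 6411 tested genes that had a name and a place on the nuclear chromosomes. Of these, 874 changed in the mutant and 146 in the overexpressor. Probe sets without a gene name could not be placed, so a block among them could be missed. Over the 9 sets of changed genes, taken per comparison and direction, the permutation p lay between 0.254 and 0.962 before any adjustment.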

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

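Both values were chosen after the data were seen, and no explanation, technical or biological, was tested for either. They belong to control probe sets outside the tests, and each lay more than 1 log2 unit above both wild-type arrays in both mutant arrays. The control for the Arabidopsis 25S ribosomal RNA was 3.47 log2 units higher in the mutant than in wild type, at 8.03 and 11.2 against 6.42 and 5.86, and stood at 6.28 and 6.61 in the overexpressor. The control named after the sequence record U12639 was 2.86 log2 units higher in the mutant, at 4.81 and 4.84 against 1.97 in each wild-type array, and stood at 1.97 and 2.00 in the overexpressor.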

How the results depend on the processing

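The exchanged replicate numbers, the fit without the probe sets printed to more decimals and the plastid list were added after the data were examined. OPS in the overexpressor kept its direction and its call under each of the 13 alternatives in which it was examined; its mean left it out at a minimum of 6. Of the named genes, the 9 rises in the overexpressor against wild type kept theirs where tested, as did 7 of 10 rises and 8 of 10 falls in the mutant, and none of the 10 falls in the overexpressor kept its call throughout. None of these changed sign. Of the list members that passed, 1 of 8 in the mutant, 0 of 1 in the overexpressor and 1 of 11 between the lines kept the call without each array in turn. With only 2 arrays per group, leaving out 1 leaves a lone array assumed to vary like the other groups. It also leaves 2 residual degrees of freedom instead of 3, so a lost call need not rest on that particular array. Leaving out a mutant array leaves every change of the overexpressor against wild type as it was. The lower counts and lost calls there come from the estimate of the spread and its degrees of freedom. The cause of the other moves from leaving out an array was not tested, and the overexpressor count rose without overexpressor array 1. Requiring a 2-fold change as well left 493 calls in the mutant, 185 in the overexpressor and 642 between the lines. Without a filter the mutant count was 1009, the number of probe sets with wild type between was 1006, and 2, 1 and 0 lists passed camera, the anthocyanin list among the 2. With a mean of at least 6 the overexpressor count was 191, and no list passed in the mutant because the cold list then had too few members to test. In fits of only the 2 groups compared the overexpressor count was 75. The causes of the other shifts were not tested. With an estimated correlation 0 lists passed in the mutant, and with fry 1 list passed between the lines, the brassinosteroid-induced growth genes. Leaving out each array in turn gave counts of 167 to 1807 in the mutant, 57 to 373 in the overexpressor and 363 to 1931 between the lines. It gave -0.16 to 0.03 for OPS in the mutant, r = 0.177 to 0.376, 211 to 1400 probe sets with wild type between, and 1 to 2, 0 to 1 and 0 to 3 lists.

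The replicate numbers as given do not pair the samples throughout. Deviations of same-numbered arrays correlated at -0.24 between wild type and mutant, 0.156 between wild type and overexpressor and -0.305 between mutant and overexpressor. Exchanging the mutant numbers would make each of these positive. A batch shared under other numbers, which the main fit ignores, therefore stays open and was not tested. With the replicate number as a block the counts were 1166, 118 (91 higher and 27 lower) and 1579, and 1058 probe sets had wild type between. With the mutant numbers exchanged they were 2335, 771 (382 higher and 389 lower) and 2972. Without the probe sets printed to more decimals they were 1877, 427 and 2422. Signal over background limits OPS in the mutant and the 22 list genes under the filter, of which DFR and UF3GT passed in the mutant in the fit without a filter.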

Other observations

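The families, the plastid list, the count of transcripts off in one group and all tests of explanations below were chosen after the results were seen. Among gene families formed from symbols, the expansins (EXPA) were lower in the overexpressor than in wild type, with a median of -0.67 over 6 members (camera adjusted p = 0.0362 over the added families; adjusted p = 0.909 with an estimated correlation). Quantile normalization and median centring gave -0.65 and -0.68. The estimated correlation of the expansins was -0.117, so their larger p with an estimated correlation does not come from members that moved together. EXPA9 fell 2.06-fold (SE 0.143 log2 units, adjusted p = 0.0181) and was the 1 member to pass. The xyloglucan-modifying XTH family had a median of -0.53 (camera adjusted p = 0.0502), negative under both scalings, and XTH19 fell by 1.07 log2 units (SE 0.177). In the mutant EXPA8 and XTH20 rose 2.59-fold and 2.07-fold, with family medians of 0.01 and -0.13 that did not pass. UGT73D1, a glycosyltransferase gene, rose 5.03-fold in the overexpressor (SE 0.267, adjusted p = 0.00984) and CYP71B23, a cytochrome P450 gene, rose 2.49-fold (SE 0.182). The glutathione transferase gene GSTU20 rose 2.83-fold in the mutant (SE 0.162) and GSTU25 fell 2.24-fold in the overexpressor (SE 0.223).

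In the overexpressor, 22 probe sets had a mean above 6 against a wild-type mean below 3.5, and 0 had the opposite, while in the mutant 2 went this way and 4 the opposite. Besides OPS they include AT1G19960, AT3G28510, AT1G13470, AT5G41280, cwINV6, and, under the filter, AT1G10340, AT5G52760 and the chitinase gene CHI. Stretches of another accession around a few loci cannot be told apart from other sources: 0% of the 11 named genes other than OPS had another within 50 neighbouring measured genes, but the other 10 probe sets have no gene name here and could not be placed. A different accession as background of the whole overexpressor line likewise cannot be told apart from an effect of OPS, since the labels do not give it and only 1 gene, AT3G60420, had a second probe set, which moved by 0.07. A summary of the overexpressor arrays apart from the others stays open and untested. These arrays differed from the others in their highest values and in the number of probe sets printed to more decimals. Such processing could not be told apart from an effect of the line.

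In the mutant, COR27, AT4G33980, COR47 and LTI30 were lower together. The cold and abscisic acid list, COR15B included, had a median of -1.06 without mutant array 1 (camera adjusted p = 0.0125) and -1.45 without mutant array 2 (0.00366), but its call over all arrays was lost with an estimated correlation (adjusted p = 0.411 with an estimated correlation). COR27 and COR28 also follow the time of day, so 4 evening and night phased genes were examined. PWD and DPE1, of starch breakdown, fell by 1.73 (SE 0.189, adjusted p = 0.00354) and 1.74 (SE 0.183), and AT1G56300 fell by 1.81 (SE 0.148), whereas GI differed by -0.295 (SE 0.168, adjusted p = 0.286), at 0.295 the smallest of the 4 in absolute size. A harvest at another time of day may account for part of this and cannot be told apart from an effect of the mutation on daily timing, since GI lay in the same direction by less than the other 3 and the labels used here give no harvest times.

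Plastid-encoded transcripts had a median change of -0.32 over 65 genes in the overexpressor, where 11 fell (camera adjusted p = 7.68e-06; adjusted p = 0.957 with an estimated correlation), and of -0.08 in the mutant, where 8 fell. Wild-type array 1 is a candidate source, since without it the median in the overexpressor was -0.05 and in the mutant 0.145, and without wild-type array 2 they were -0.63 and -0.44. In the overexpressor against the mutant, a difference that no wild-type array enters, the median was -0.235. No member passed there (camera adjusted p = 0.147; adjusted p = 0.918 with an estimated correlation). The plastid median was 11.07 and 10.53 in the wild-type arrays, 10.38 and 10.35 in the mutant and 10.12 and 9.82 in the overexpressor, where the gap between 3' and 5' GAPDH signals was 1.42 and 1.12, 1.80 and 1.39, and 1.92 and 1.72 log2 units in the same order. The 8 nuclear photosynthesis genes had a median of -0.065 (SE of the mean 0.0498), which by the rule chosen went against fewer or smaller chloroplasts. These transcripts do not measure the number or size of chloroplasts, and the plastid median without wild-type array 1 was as small. The rule therefore cannot decide, and fewer or smaller chloroplasts stay open. RNA quality and an effect of OPS on plastid transcripts stay open and untested, and petG was at -1.62 and atpF at -1.49 without wild-type array 1 (adjusted p = 0.0945 and 0.0425).

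Probe sets printed to more decimals differed from the others in the spread of their replicates. In the mutant 33.3% of 411 such tested probe sets differed between the replicates by under 0.005 log2 units, against 1.19% of the others, and 20.2% differed by over 0.5, against 5.79%. PPDK is among them, with mutant values of 6.23 on both arrays. So are AT5G48490 and AT1G13650, with wild-type values of 7.40 and 9.20 and of 3.45 and 4.97. In wild type 38.7% and in the overexpressor 37.6% of such probe sets differed by under 0.005.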
